A study of Homo sapiens with 6 samples.

How the data were processed

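RNA of DLD-1 cells, a human colorectal adenocarcinoma line, was sequenced after transfection with a control siRNA or with siRNA against AHR, which encodes the aryl hydrocarbon receptor, a ligand-activated transcription factor. The labels name 6 samples, 3 per group, and the sample titles gave each sample its group and replicate number. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made by standard Illumina protocols. The siRNA sequences, the time after transfection, the selection of RNA, the strandedness, the read length and the handling of reads that map to several places are not given in the sources used here. No label says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

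The authors deposited a table of counts for each sample, with 1 whole number per versioned Ensembl gene ID and no header. Per the submitters' processing notes, TopHat2 2.0.11, TopHat and HTSeq were used and the builds were hg19 and GRCh37, with no role or order stated. The IDs include ones that belong to GRCh38 annotations, so the build behind the deposited counts is uncertain and no coordinates were taken from the tables. Each table listed 60483 genes and no rows without a gene, and 30025 genes had no count in any library. Of the IDs, 56321 were found in a table of gene names and 41124 had a symbol there. Genes without a symbol were tested and kept out of the rule for named genes. All 37 genes of the mitochondrial genome were listed at 0 in all 6 libraries.

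The library totals were 14412028, 15037145 and 13585529 counts for control siRNA replicates 1 to 3, and 11567736, 12937058 and 12895480 counts for AHR siRNA replicates 1 to 3. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (14900 genes), libraries were scaled by TMM, and a quasi-likelihood model with the group as its only term was fitted and tested with glmQLFTest. A gene was called changed at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over all 14900 genes. TMM factors were 0.926 to 0.965 in control siRNA and 1.05 to 1.06 in AHR siRNA libraries. CPM values are scaled to the TMM-adjusted sum of the counts on tested genes, with the SD over 3 libraries. The standard error (SE) of a log2 fold change was its size divided by the square root of the test's F value. The biological coefficient of variation, from the common dispersion, was 0.066. At this depth and with the abundance-dependent dispersion trend fitted to the data, the comparison was simulated on 14651 genes. It recovered 40.8% of the genes changed 1.25-fold, 70.0% of those changed 1.5-fold, 87.5% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls. Only 49, 50, 48 and 50 genes were changed at these folds, far fewer than were called in the data. The adjusted p threshold was therefore harder to pass in the simulation, and neither its recovery nor its false calls carry over to the data.

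Before the data were examined, 34 gene lists, the tests, the alternatives and a rule for the genes to be named were fixed. The lists cover AHR biology, cell cycle, metabolism, intestinal lineage, signalling, stress and RNA interference, with markers of fibroblasts, leukocytes and endothelium and genes of RNA quality as checks. Members were matched by current symbol and then by the GENCODE 29 name of the same ID. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 31 lists. In the simulation the planted list was found, and 3 other lists that held randomly changed genes were called. The rule for naming genes took AHR and each tested canonical AHR target. It also took, among genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, the 12 largest rises and the 12 largest falls, and the 10 smallest p-values. In each list it took up to 4 called members with the smallest p. In some of the called lists, members outside the rule that moved against the list are also named, and are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

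Each result was recomputed with DESeq2 size factors, upper-quartile factors or library totals alone. It was also recomputed with no filter or a filter of at least 1 CPM in 3 samples, and with a replicate block. Other runs left out each library in turn, or the ribosomal, mitochondrial and 20 most abundant genes. Single genes and counts of called genes, but not gene lists, were recomputed with the DESeq2 1.42.0 Wald test and with limma-voom. Further alternatives were an adjusted p under 0.01, edgeR's glmTreat with a minimum fold of 1.5, camera with an estimated correlation and limma's fry. Removal of GC and length trends by loess (span 0.4, on the 99.4% of tested genes with a GENCODE 29 transcript) and thinning to the smallest total were added after the data were seen. The library totals given here include all deposited counts. Whether the libraries of a group were copies was checked by a chi-square of their counts. The statistic per degree of freedom, about 1 for counting noise alone, ran from 1.54 for control siRNA replicates 2 and 3 to 8.59 for control siRNA replicates 1 and 2. No pair was identical. The next lowest pair, AHR siRNA replicates 2 and 3, was at 3.31. Control siRNA replicates 2 and 3 thus came closest to counting noise, and they may not be independent.

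For words in 3' UTRs, the 3' UTR of the principal (or else the longest) protein-coding GENCODE 29 transcript was taken where it had at least 50 bases, which left 12183 tested genes. For each of 16188 7-base words found in at least 50 genes, the log2 fold change was regressed on presence of the word, with UTR length and dinucleotide composition as covariates, and the t values were centred on their median and divided by their scaled median absolute deviation (robust z). On shuffled fold changes the robust z ran from -3.93 to 3.89, and a word planted with a log2 effect of -0.25 was found as the lowest at -8.11. The spread was wider for the difference of a library from the others of its group. It reached -5.17 for AHR siRNA replicate 1 and 5.34 for control siRNA replicate 1. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for this step.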

Results

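The transcriptome of DLD-1 colorectal cancer cells was measured by RNA-seq after transfection with control siRNA (3 libraries) or AHR siRNA (3 libraries), to find the genes regulated by AHR in these cells. AHR encodes the aryl hydrocarbon receptor, a ligand-activated transcription factor that induces detoxification enzymes. The libraries held 11567736 to 15037145 counts, with the 3 lowest totals in the AHR siRNA group, and 22985 to 23898 genes had at least 1 count. Libraries of the same group were alike, with Pearson correlations of log2 CPM across genes of 0.991 to 0.994, against 0.957 to 0.963 between groups. The first principal component held 78.2% of the variance and separated the groups, and the second held 8.35% and set control siRNA replicate 1 apart from the rest of its group.

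The AHR transcript was lower in the AHR siRNA libraries, which retained 70.8% of the control level. AHR (ENSG00000106546.11, on chromosome 7) stood at 117, 144 and 132 CPM in control siRNA replicates 1, 2 and 3 and at 95.8, 87.4 and 95.0 CPM in AHR siRNA replicates 1, 2 and 3. The means were 131 ± 14 CPM (SD, n = 3) and 92.7 ± 4.7 CPM (SD, n = 3), a log2 fold change of -0.50 (SE 0.08, edgeR adjusted p = 1.98e-05), with all 3 AHR siRNA libraries below all 3 control libraries. Of the other genes of the AHR receptor complex, HSP90AA1, the inducible form of the chaperone that holds the receptor in the cytoplasm, fell to 49.4% of control. The co-chaperone PTGES3 fell to 61.4% and the exportin XPO1 to 66.4%, while the kinase gene SRC rose to 145%. Of the 10 tested members of this list, 6 were lower, 1 was higher and 3 were not called (camera adjusted p = 0.123, and 0.000552 with no filter; adjusted p = 0.360 with an estimated correlation among the filtered genes).

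Most canonical AHR target genes were lower in AHR siRNA cells, though some carry 3' UTR words that are weighed below. Of 15 tested members, 11 were lower, 3 were higher and 1 was not called, with the same counts when adjusted over the list alone. SLC7A5, a transporter of tryptophan and other large amino acids, fell from 915 ± 29 to 204 ± 21 CPM (SD, n = 3 each), a log2 fold change of -2.16 (SE 0.08, edgeR adjusted p = 1.07e-13). The aldehyde dehydrogenase gene ALDH3A1 fell to 48.8% of control, the growth factor gene EREG to 58.5%, the cytochrome gene CYP1B1 to 59.7%, the ADP-ribosyltransferase gene TIPARP to 59.7%, and the quinone reductase gene NQO1 to 79.3%. The efflux pump gene ABCG2 fell to 32.2% and UGT1A1 to 17.5% of control, the latter from 2.68 CPM at a log2 fold change of -2.52, which was -3.15 without AHR siRNA replicate 1. UGT1A6 fell to 56.9%, NFE2L2 to 68.1% and NFE2L1 to 83.6%. UGT1A1 and UGT1A6 share exons, so their separate values are uncertain. CYP1A1, a commonly used readout of AHR activity, was close to the floor at 1.72 ± 0.85 and 1.69 ± 0.33 CPM (SD, n = 3 each), with a log2 fold change of -0.03 (SE 0.33, edgeR adjusted p = 0.948), and a difference of that size was not detectable at this depth and changed its sign with the scaling. AHRR, which encodes the AHR repressor, was higher at a log2 fold change of 0.37 (SE 0.14, edgeR adjusted p = 0.0299), LTBP4 was higher at 0.33 (SE 0.12), and VAV3 rose from 0.197 to 1.32 CPM. The control level of VAV3 rested on 5, 2 and 1 counts, and its log2 fold change of 2.70 was 3.48 without control siRNA replicate 1.

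The list median was a log2 fold change of -0.74, and camera called the list lower (adjusted p = 0.00623; adjusted p = 0.168 with an estimated correlation). AHRR lost its call without control siRNA replicate 1 (log2 fold change 0.32, edgeR adjusted p = 0.0518), without control siRNA replicate 2 (0.32, 0.0872), without AHR siRNA replicate 3 (0.22, 0.224), with GC and length trends removed (0.26, 0.0939) and with DESeq2 (0.36, 0.0696), and its adjusted p ran from 0.00529 to 0.224 over all alternatives. LTBP4 lost its call without control siRNA replicate 1 (0.19, edgeR adjusted p = 0.143), without AHR siRNA replicate 2 (0.29, 0.0936) and with GC and length trends removed (0.11, 0.398), within a range from 0.00397 to 0.398, and NFE2L1 with library totals alone (-0.11, edgeR adjusted p = 0.181, the highest of its alternatives, with the lowest at 1.13e-05).

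**Figure D1:**
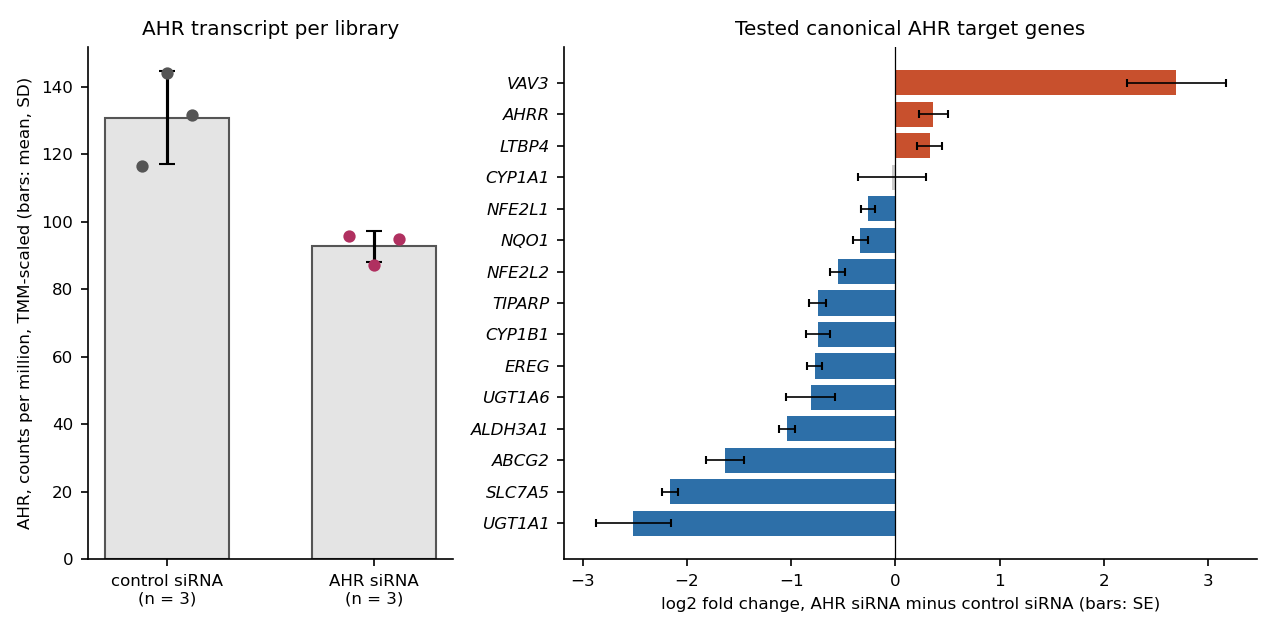
AHR in CPM per library (left; points are libraries, bars are means and error bars SDs of 3 libraries) and the log2 fold change, AHR siRNA minus control siRNA, of the 15 tested canonical AHR target genes (right; error bars are SE; blue and orange mark lower and higher calls, grey no call). The AHR siRNA libraries lay between 87.4 and 95.8 CPM, all below the control libraries, and 11 targets were lower.

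The knockdown went with changes across the transcriptome. Of 14900 tested genes, 8953 (60.1%) were called changed by edgeR at an adjusted p under 0.05, 4474 higher and 4479 lower in AHR siRNA cells, and the groups did not overlap for 63.7% of the tested genes, against 10% by chance. At a fitted fold of at least 2, 1966 genes were called, 1153 higher and 813 lower, and at a fold of at least 4, 142 were higher and 67 lower. AHR itself changed by less than most of these: 5348 called genes had a larger fold change, and 2455 of the lower genes fell further than AHR. The median size of a called change was 0.59 on the log2 scale. The split into higher and lower genes depended on the scaling: with library totals alone 5885 of 9090 called genes (64.7%) were higher, against 4474 of 8953 with TMM, and the log2 fold change of the median gene shifted by 0.15.

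Among genes with a mean of at least 5 CPM, the largest fall was in CCL20, which encodes a chemokine that attracts lymphocytes and dendritic cells. It fell 12.1-fold, from 12.8 ± 1.8 to 1.04 ± 0.30 CPM (SD, n = 3 each), with a log2 fold change of -3.60 (SE 0.21, edgeR adjusted p = 5.13e-11). BIRC3, a ubiquitin ligase gene of the NF-kB pathway, fell 9.99-fold (log2 fold change -3.32, SE 0.12), the membrane protein gene EMP1 9.74-fold, and CA2, which encodes carbonic anhydrase of colonocytes, 7.63-fold. ALPP fell 7.57-fold, the alarmin gene IL33 6.76-fold, SDCBP2 6.06-fold, the complement decay-accelerating factor gene CD55 5.60-fold, the acute-phase gene SAA2 5.34-fold, the lipid transporter gene ABCA12 5.24-fold, the scavenger receptor gene OLR1 5.24-fold from 526 to 100.4 CPM, and the prion protein gene PRNP 5.01-fold. CMPK1, a pyrimidine nucleotide kinase gene, and the Golgi membrane gene GOLM1 were also among the 10 smallest p-values and fell 4.72-fold and 4.03-fold. ALPP and SAA2 have near-identical paralogs, so their values are uncertain.

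Among genes with a mean of at least 5 CPM, the largest rise was in KRTAP3-1, a keratin-associated protein gene, which went from 1.53 ± 0.54 to 46.7 ± 0.7 CPM (SD, n = 3 each), 30.5-fold, with a log2 fold change of 4.93 (SE 0.14, edgeR adjusted p = 1.13e-14). ENTPD8, which encodes a nucleotide-hydrolysing enzyme of the cell surface, rose 28.7-fold from 2.51 ± 0.47 to 72.1 ± 6.8 CPM (log2 fold change 4.84, SE 0.13). AGXT, the peroxisomal alanine-glyoxylate aminotransferase gene, rose 15.3-fold and the long non-coding RNA LINC02593 11.4-fold, both to 10.7 CPM. The cystatin gene CST1 rose 8.37-fold, KLHL24 7.11-fold, the cilium gene RSPH1 6.79-fold, the histone gene H2BC5 6.77-fold, the growth factor gene FGF20 6.47-fold, the transcription factor gene NFATC4 6.46-fold, PBXIP1 6.43-fold and the immediate early gene FOSB 6.06-fold. TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose 5.41-fold from 53.9 ± 4.3 to 292 ± 7 CPM (SD, n = 3 each), and DPYSL3 rose 4.36-fold. CST1 and H2BC5 belong to families of near-identical copies and are uncertain.

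Several of the genes named here carry the 7-base word GACTTAA or CACAACA in their 3' UTR, the pair of words with the lowest scores among 16188 words tested on these same fold changes. They included 5 of the 12 largest falls (EMP1, IL33, CD55, OLR1 and PRNP), the AHR targets SLC7A5, ABCG2, CYP1B1, NQO1, NFE2L1 and CYP1A1, and also CMPK1, GOLM1, DSG2, MCM10, KLK10, LDHA, CCND1, DPP4, PSAT1, PDIA6, PDK1 and COL4A1. None of the 11 largest rises with an annotated 3' UTR held either word. Of the 15 tested AHR targets, 6 (40.0%) held a word, against 17.2% of all 12183 genes with a 3' UTR. The falls of the lower ones among these 6 can therefore not be credited to loss of AHR alone. ALDH3A1, EREG, TIPARP, UGT1A1, UGT1A6 and NFE2L2 were lower and held neither word. That alone does not credit their falls to loss of AHR, since 31.6% of all genes with neither word were lower too. Across 12183 genes, 46.3% of the 2096 genes with either word were lower and 23.1% were higher, against 31.6% and 31.8% of the 10087 genes with neither. Because the words were picked on these fold changes, these shares are not independent evidence of the words' direction. Both words also occur in the coding part of the AHR transcript on chromosome 7 (GRCh38, GENCODE 29): GACTTAA at 17309995 to 17310001 in exon 2 and at 17339551 to 17339557 in exon 10, and CACAACA at 17339831 to 17339837 and at 17339951 to 17339957 in exon 10.

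**Figure D2:**
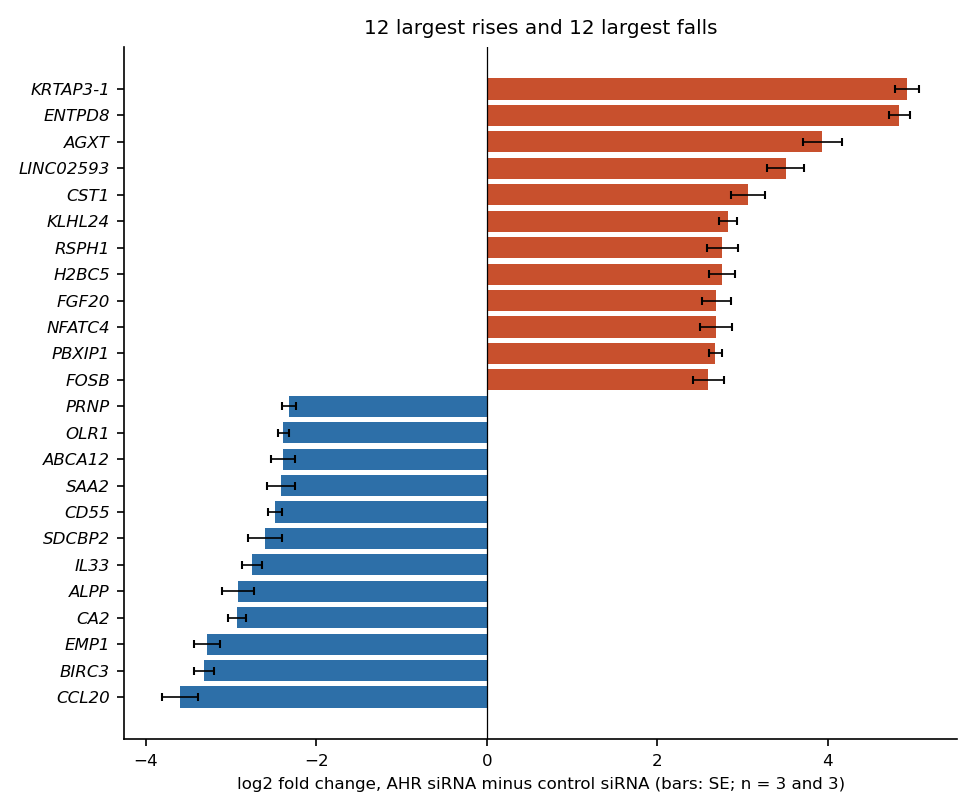
Log2 fold change, AHR siRNA minus control siRNA, of the 12 largest rises (orange) and 12 largest falls (blue) among genes with a symbol, a mean of at least 5 CPM and no overlap between the groups (error bars are SE, n = 3 per group). The values run from -3.60 for CCL20 to 4.93 for KRTAP3-1.

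Genes of cell division fell together. All 30 members of the mitosis list and all 30 members of the DNA replication list were called lower, over all genes tested and when adjusted over the list alone, with median log2 fold changes of -1.33 and -1.13, or 39.7% and 45.8% of control. Among mitotic genes, CDC20, the activator of the anaphase-promoting complex, fell from 364 ± 17 to 102 ± 2 CPM (SD, n = 3 each), a log2 fold change of -1.83 (SE 0.07, edgeR adjusted p = 1.07e-13). The cytokinesis gene ANLN fell to 25.4% of control, the spindle gene DLGAP5 to 30.1% and the checkpoint kinase gene BUB1 to 32.4%. Among replication genes, the origin licensing factor gene CDC6 fell to 28.5%, MCM10 to 32.1%, and the helicase subunit genes MCM5 and MCM4 to 38.1% and 40.7%. Camera called both lists lower (adjusted p = 3.04e-21 for mitosis and 2.04e-18 for replication), and with an estimated correlation neither call held (adjusted p = 0.168 for each).

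Genes of NF-kB signalling and inflammation also fell. Of 21 tested members, 19 were lower, 1 was higher and 1 was not called, with the same counts when adjusted over the list alone, and the median log2 fold change was -0.99. Besides CCL20 and BIRC3, the chemokine gene CXCL8 fell to 33.0% of control, from 58.1 ± 6.8 to 19.2 ± 0.9 CPM (SD, n = 3 each), and NFKBIA, the inhibitor that NF-kB itself induces, to 38.6%. PTGS2, named after its value was seen, was the 1 member that rose, from 3.01 ± 0.71 to 8.61 ± 1.27 CPM (SD, n = 3 each). Camera called the list lower (adjusted p = 5.88e-08; adjusted p = 0.0957 with an estimated correlation).

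The lists of glycolysis and of the unfolded protein response were lower by smaller amounts. Of 21 glycolysis genes, 16 were lower and 4 were higher, with the same counts when adjusted over the list alone and a median log2 fold change of -0.38. The lactate exporter gene SLC16A3 fell to 41.3% of control, LDHA to 45.1% and PKM to 56.9%, whereas PDK1, which holds pyruvate out of the mitochondrial cycle, rose to 171%. The other higher members, named after their values were seen, were PFKL, PFKM and PFKFB4, with log2 fold changes of 0.32, 0.43 and 0.47. Of 26 genes of the unfolded protein response and of ATF4, 15 were lower and 1 was higher, again the same when adjusted over the list alone, and the median was -0.37. The disulfide isomerase genes PDIA4 and PDIA6 fell to 52.8% and 57.8%, and the serine synthesis genes PSAT1 and PHGDH to 54.2% and 59.8%. DDIT4, named after its value was seen, was the higher member at 0.45 (SE 0.16). Camera called both lists lower (adjusted p = 0.00615 for glycolysis and 0.00183 for the unfolded protein response), and with an estimated correlation neither call held (adjusted p = 0.360 and adjusted p = 0.451).

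Targets of Wnt signalling and histone genes were higher. Of 22 tested Wnt/beta-catenin target genes, 15 were higher and 4 lower, with the same counts when adjusted over the list alone and a median log2 fold change of 0.38. The stem cell transcription factor gene ASCL2 rose to 265% of control, from 53.4 ± 7.7 to 141 ± 9 CPM (SD, n = 3 each), and PROX1 to 345%. Of the lower members, CCND1, which encodes cyclin D1, fell to 47.8% and the cell cycle phosphatase gene CDC25A to 47.2%, while TCF7 and CD44, named after their values were seen, changed by -0.73 and -0.20 on the log2 scale. Camera called the list higher (adjusted p = 0.0141; adjusted p = 0.239 with an estimated correlation). Of 9 tested replication-dependent histone genes, 6 were higher and none lower, against 7 higher when adjusted over the list alone, and the median was 1.05. H2BC5, H2AC6, H2BC12 and H2BC21 rose to 677%, 448%, 190.1% and 258% of control. Histone genes have near-identical copies, so single values are uncertain (camera adjusted p = 0.00615; adjusted p = 0.168 with an estimated correlation). The selection of RNA is not given in the sources used here, so which forms of the histone transcripts were counted is not known. These rises are therefore no measure of histone expression in dividing cells.

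**Figure D3:**
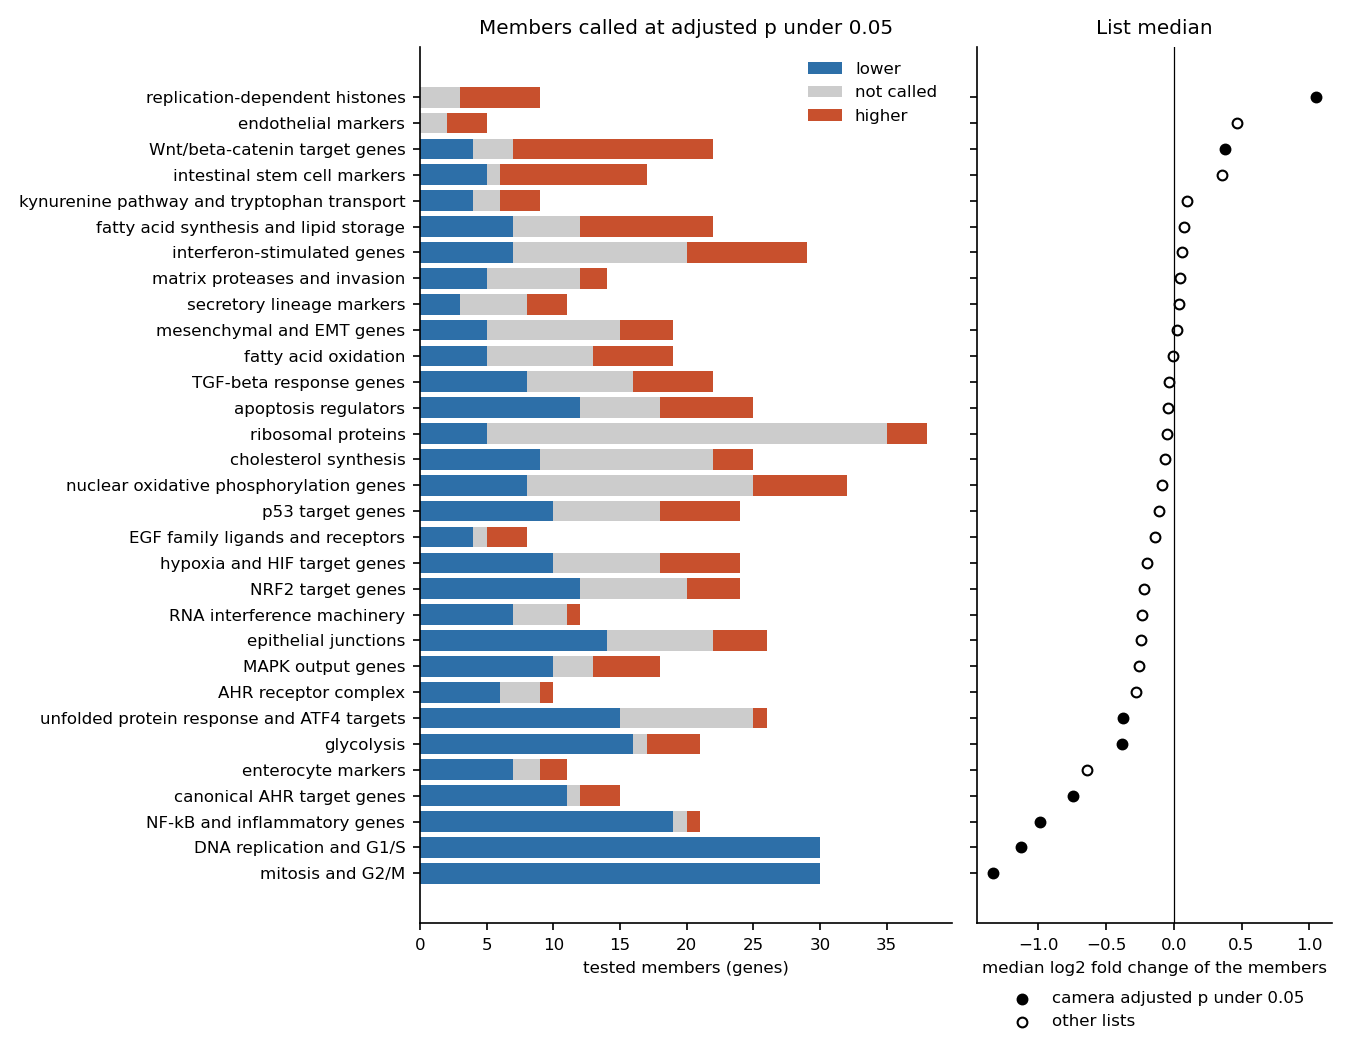
Tested members called lower, higher or not called at an adjusted p under 0.05 in each of the 31 lists tested (left, in genes), and the median log2 fold change, AHR siRNA minus control siRNA, of the members (right; filled points are the 8 lists called by camera). Medians run from -1.33 for mitosis to 1.05 for replication-dependent histones.

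Lineage markers of the intestine were not called as groups by camera among the filtered genes, while with no filter the stem cell list was called higher (camera adjusted p = 0.00379) and the enterocyte list lower (0.0225). Among the filtered genes the values were adjusted p = 0.294 with an estimated correlation for stem cell markers and adjusted p = 0.552 with an estimated correlation for enterocyte markers. Of 17 stem cell markers, 11 were higher and 5 lower (median 0.36, camera adjusted p = 0.0765): LGR5, a receptor that marks crypt stem cells, rose to 188% of control and LRIG1 to 277%. ALDH1A1, with a mean of 1.71 CPM, had 2, 0 and 0 counts in the control siRNA libraries and 51, 52 and 28 in the AHR siRNA libraries. Of 11 enterocyte markers, 7 were lower and 2 higher (median -0.64, camera adjusted p = 0.123): besides CA2, the transcription factor gene KLF4 fell to 55.7% and the peptidase gene DPP4 to 50.6%, whereas VIL1, which encodes the microvillus protein villin, rose to 449.8%. Of 11 secretory lineage markers, 3 were lower and 3 higher (median 0.04, with a mean of -0.16 and a test pointing lower, camera adjusted p = 0.710). MUC13 fell to 44.2% and KLK10 to 43.5%, while the Notch ligand gene DLL1 rose to 220.2% of control. Of 26 epithelial junction genes, 14 were lower (15 when adjusted over the list alone) and 4 higher (median -0.24, camera adjusted p = 0.0607), with the desmosomal cadherin gene DSG2 at 20.9% of control. The junction list was called lower with no filter (camera adjusted p = 0.000448), without control siRNA replicate 1 (0.0338), without AHR siRNA replicate 2 (0.0460) and with GC and length trends removed (0.0258), and its camera adjusted p reached 0.263 with an estimated correlation. Of 19 mesenchymal genes, 5 were lower and 4 higher (median 0.02 and mean 0.06, with a test pointing lower, camera adjusted p = 0.822). Among these, TGFBI fell to 52.6% and COL4A1 rose to 226% of control.

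Markers of cells other than epithelium were near the floor. Of the fibroblast, leukocyte and endothelial markers, 3, 3 and 5 were tested, of which 1, 2 and 3 were higher and 1, 1 and 0 lower. The highest of the called ones was EGFL7 at 7.04 ± 0.43 and 9.70 ± 1.80 CPM (SD, n = 3 each), and the others, among them PDGFRB, CD14 and VWF, lay under 5 CPM in both groups. Only the endothelial list had enough members for camera (median 0.46, adjusted p = 0.442). Of 38 ribosomal protein genes, 5 were lower and 3 higher, against 5 and 1 when adjusted over the list alone (median -0.05, camera adjusted p = 0.710), and this median changed its sign with the scaling.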

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

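The removal of GC and length trends and the thinning were chosen only after the result was seen. Of the values of single genes under alternatives, 731 kept direction and side of the threshold, 9 lost the call and 8 changed sign. Of those of lists, 453 kept both, 8 lost the call, 30 gained one and 35 changed sign. Of the counts of calls, 101 stayed within 1.5 times, 1 was lower and 2 were higher. The changed genes numbered 7298 (adjusted p under 0.01) to 9598 over the alternatives and 8050 to 8993 without each library in turn. No gene called in the TMM analysis was called in the opposite direction by an alternative, and genes that changed sign but lost their call were not counted. AHR was called under all alternatives, at log2 fold changes from -0.58 to -0.35, and 150 to 156 of the named genes were called. The gene lists called by camera numbered 8, against 14 with no filter (adding the lists of the AHR receptor complex, NRF2 targets, stem cell and enterocyte markers, epithelial junctions and MAPK output), 0 with an estimated correlation and 24 with fry, which compares a list with no other genes. A replicate block gave 9598 changed genes and called the lists of epithelial junctions (camera adjusted p = 0.0495) and MAPK output (0.0455), but the deviations of same-numbered libraries correlated at 0.193, -0.040 and 0.154, and AHR siRNA replicate 3 correlated better with control siRNA replicate 2 (0.160) than with its own number. With library totals alone 85.8% of the calls were kept. Low counts limit the values of CYP1A1, VAV3, UGT1A1 and the markers of other cell types.

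The following values, a log2 fold change for CYP1A1 and list medians otherwise, changed sign in results that were not called, and the cause was not tested. With upper-quartile factors they were 0.0502 for CYP1A1, 0.011 for cholesterol synthesis, 0.0759 for fatty acid oxidation, 0.0393 for TGF-beta response, 0.0354 for apoptosis and 0.0316 for ribosomal proteins. With library totals alone they were 0.122 for CYP1A1, 0.0419 for p53 targets, 0.0801 for cholesterol synthesis, 0.146 for fatty acid oxidation, 0.00903 for the EGF family, 0.109 for TGF-beta response, 0.103 for apoptosis, 0.0649 for oxidative phosphorylation and 0.102 for ribosomal proteins. Fatty acid oxidation was at 0.00493 with at least 1 CPM in 3 samples, and with a replicate block it was at 0.00111 and CYP1A1 at 0.00753. With GC and length trends removed the medians were 0.00834 for fatty acid oxidation, -0.131 for secretory markers, -0.0329 for mesenchymal genes and -0.0781 for matrix proteases. With thinning they were 0.0784 for CYP1A1, 0.0469 for fatty acid oxidation and -0.0440 for secretory markers, and limma-voom gave 0.0588 for CYP1A1. Without each library in turn, CYP1A1 ran from -0.246 to 0.433, the kynurenine list from -0.0321 to 0.193, fatty acid oxidation from -0.0437 to 0.0816, secretory markers from -0.0766 to 0.217, mesenchymal genes from -0.0577 to 0.0641, apoptosis from -0.127 to 0.0188, oxidative phosphorylation from -0.130 to 0.00163 and ribosomal proteins from -0.112 to 0.0434.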

Other observations

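Of 9 tested genes of the kynurenine pathway and tryptophan transport, 4 were lower and 3 higher, against 4 and 4 when adjusted over the list alone (median 0.09, with a mean of -0.11 and a test pointing lower, camera adjusted p = 0.696). Besides SLC7A5, its partner subunit gene SLC3A2 fell by 0.53 and the cystine transporter gene SLC7A11 by 0.87 on the log2 scale, whereas QPRT, an enzyme gene of NAD synthesis, rose by 1.99. Of 24 NRF2 target genes, 12 were lower and 4 higher (median -0.22, camera adjusted p = 0.0962, and 0.000468 with no filter; adjusted p = 0.629 with an estimated correlation among the filtered genes), with HMOX1 and GCLM each at a log2 fold change of -1.54. Of 24 p53 target genes, 10 were lower and 6 higher (median -0.11, camera adjusted p = 0.442), with CDKN1A, a cell cycle inhibitor gene, at -1.37 and TP53I3 at 1.17. Of 18 MAPK output genes, 10 were lower and 5 higher (median -0.25, camera adjusted p = 0.0607), with EPHA2 at -1.03 and DUSP6 at -0.90. The MAPK output list was called lower with no filter (camera adjusted p = 0.000552), without control siRNA replicate 1 (0.0171), without AHR siRNA replicate 2 (0.0455) and without AHR siRNA replicate 3 (0.0277), and its camera adjusted p reached 0.629 with an estimated correlation. Of 8 EGF family genes, 4 were lower and 3 higher (median -0.14, camera adjusted p = 0.666), with EGFR at -1.60 and ERBB3 at 0.59. Of 25 apoptosis regulators, 12 were lower and 7 higher (median -0.04, camera adjusted p = 0.442), with MCL1 at -0.72 and TNFRSF10B at 0.60. In these lists, counts adjusted over the list alone were the same where no other count is given, and the medians of the p53, EGF and apoptosis lists turned positive with library totals alone.

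Genes of lipid metabolism and of other signals moved in both directions. Of 25 genes of cholesterol synthesis, 9 were lower and 3 higher (median -0.07, camera adjusted p = 0.586), with TM7SF2 at a log2 fold change of 1.95 and EBP at -0.77. Of 22 genes of fatty acid synthesis and lipid storage, 10 were higher (11 when adjusted over the list alone) and 7 lower (median 0.08, camera adjusted p = 0.586), with MLXIPL at 1.10 and ELOVL6 at -0.80. Of 19 genes of fatty acid oxidation, 6 were higher and 5 lower (median -0.00308, with a mean of 0.13 and a test pointing higher, camera adjusted p = 0.837). Of 32 nuclear genes of oxidative phosphorylation, 8 were lower and 7 higher (median -0.08, camera adjusted p = 0.837). Of 24 hypoxia genes, 10 were lower (11 when adjusted over the list alone) and 6 higher (median -0.20, camera adjusted p = 0.616), with EGLN3 at -1.20. Of 22 TGF-beta response genes, 8 were lower and 6 higher (median -0.04, camera adjusted p = 0.616), with TGFB2 at 1.44 and ID2 at -1.17. Of 29 interferon-stimulated genes, 9 were higher and 7 lower (6 when adjusted over the list alone; median 0.06, camera adjusted p = 0.616), with OAS3 at -1.13 and MX2 at 1.46. Of 14 matrix protease and invasion genes, 5 were lower and 2 higher (median 0.05, with a mean of -0.09 and a test pointing lower, camera adjusted p = 0.586), with PLAUR at -1.10. Of 12 genes of the RNA interference machinery, 7 were lower and 1 higher (median -0.24, camera adjusted p = 0.334), with AGO2 at -0.75, DICER1 at -0.58 and AGO4 at 0.84. Of the genes named in this part, EGFR, GCLM, ID2, SLC7A5, SLC7A11, ELOVL6, AGO2, MCL1, DICER1, AGO4 and TGFB2 carry the word GACTTAA or CACAACA in their 3' UTR. The medians of the cholesterol, fatty acid oxidation, oxidative phosphorylation and TGF-beta lists turned positive with library totals alone.

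The tests of the scaling of the cell division genes, of words in those genes, of genes with neither word and of nuclear copies of mitochondrial genes were chosen only after the result was seen, as were the removal of GC and length trends and the thinning.

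AHR fell by 0.50 on the log2 scale, while 59.7% of the called genes changed by more than AHR. Trends of GC content and length, a difference in depth and the gain or loss of a chromosome were argued against. With GC content and transcript length trends removed, 94.8% of the calls were kept in direction. With all libraries thinned to the smallest total (difference in depth), 94.8% were kept. The chromosome median farthest from that of all genes, on chromosome 19, lay 0.15 away (gain or loss of a chromosome). Silencing by a dominant control siRNA predicted a word with a strongly positive score, and the highest robust z was 4.16, for CGGAGAA in 289 genes. This score lay above the highest on shuffled fold changes (3.89) and below the highest within a group (5.34). Words that overlap CGGAGAA were also among the highest, such as GGAGAAA (4.12) and ACGGAGA (3.38). A word held by few genes gets a less extreme score at the same effect. The fitted log2 effect was 0.176 for CGGAGAA, against -0.210 for GACTTAA in 1274 genes. The score therefore cannot exclude a control siRNA effect of similar size through a rare word. A weaker control siRNA effect, or one spread over several control siRNAs, was not excluded either. Seed-matched silencing by an AHR siRNA predicted a word of the AHR transcript with a strongly negative score, and GACTTAA had the lowest at -9.38. Such silencing may account for part of the falls, although 33.5% of all words occur in the AHR transcript, the siRNA sequences are not given in the sources used here, and a microRNA with the same seed was not tested. Of the genes with neither word, 63.4% were called, and direct silencing through either word in the annotated 3' UTR does not reach those. The size of this share tests nothing further, since 64.4% of all 12183 genes were called and only 2096 held a word. Some of these genes may hold overlapping words with low scores, such as ACAACAA (robust z -6.71). Loss of AHR, indirect effects of silenced genes and other differences between the groups stay open for the genes with neither word.

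All 60 tested members of the replication and mitosis lists were lower, with a median log2 fold change of -1.28. With GC content and transcript length trends removed the median was -1.23, and over the scalings it was at most -1.13, with library totals alone, so neither accounts for the pattern. Direct silencing of the members through either word was argued against, since 5% of them (3 of 60) carried a word, against 17.2% of all genes with a 3' UTR. These shares were not adjusted for UTR length. Loss of AHR may account for the pattern, as may an indirect effect of genes silenced through the words. With no other AHR siRNA analysed here, the design gave no test between them. Any other difference between the groups that the labels do not record stays open as well.

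All 37 genes of the mitochondrial genome were listed at 0 in every library, while nuclear copies of mitochondrial genes held counts. Their share of all counts was 0.356% to 0.374% in control siRNA and 0.455% to 0.471% in AHR siRNA libraries. These are shares of the library totals, while the values of single copies below are TMM-scaled. Library totals alone put the log2 fold change of the median gene 0.15 higher than TMM, so the shares overstate the difference under TMM. MTATP6P1 stood at 3287 ± 154 CPM in control siRNA and 3722 ± 103 CPM in AHR siRNA libraries (SD, n = 3 each), with a log2 fold change of 0.18 (SE 0.07, edgeR adjusted p = 0.0394). MTND2P28 rose by 0.24 and MTCO1P12 by 0.36 on the log2 scale (edgeR adjusted p = 0.00233 and 0.000677). MTND4P12 was not called (0.12, edgeR adjusted p = 0.245). Whether mitochondrial reads were assigned to nuclear copies stays open, since the lowest share in a library, 0.356%, restates the pattern and gene counts do not show where a read came from. No biological explanation was tested, and the mitochondrially encoded list could not be tested.

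The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 8953 changed genes, 4474 higher, 4479 lower and 1966 at 2-fold, with 0 as the highest of the other splits for each, so that 1 of 10 splits was as large. For gene lists called by camera the real split gave 8 and the highest other also gave 8, and 3 of 10 splits were as large. Each of the other splits puts libraries of both groups on each side. Part of the group difference therefore stays in its contrast and widens its spread, so neither these gene counts nor these list counts are a chance level.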
